A study of Mus musculus with 6 samples.

How the data were processed

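Cells from the lungs of C57BL/6 wild-type mice were profiled 3 days after the animals had received either saline or the complement component C1q, instilled into the trachea at 20 µg per mouse. Per the labels' protocols, lungs were cut up and digested with Liberase and DNase, the suspension was separated on a Percoll step gradient, the middle layer was kept, and poly(A) RNA was captured on oligo-dT beads from the cell lysate. The libraries read the 5′ ends of transcripts. The values deposited by the authors are counts, whole numbers per gene symbol and sample with no normalization. The submitters' processing notes name cutadapt 2.1.0, Bowtie2 2.4.2 and the build GRCm38, while the counting step, the annotation and whether reads or unique molecules were counted are not given in the sources used here. A 5′-end count limited to transcript starts near the cap carries no information on the body of the transcript. Whether reads elsewhere in a gene were counted is not given in the sources used here. Because strand handling is also not given in the sources used here, overlapping and antisense genes cannot be told apart from these counts.

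Samples were assigned to saline (n = 3) or C1q (n = 3) from their treatment label, and numbered 1 to 3 within each group in the order of deposition. These numbers pair nothing. The treatment text of all 6 samples describes the C1q instillation alone, so the saline group rests on its treatment label. The labels speak of mice but do not say that each sample is a separate animal, so p-values of single genes measure the spread between these samples. All 15 pairs of libraries differed by more than counting noise, with a chi-square per degree of freedom of 5.20 to 16.7. Separate preparations of 1 lysate can differ by more than counting noise too, so this leaves open whether the libraries came from separate animals, and each was counted as 1 sample.

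Of 26890 genes listed, edgeR's filterByExpr kept 13473, which held 98.2% to 99.3% of the counts of each library. The counts were scaled by TMM and tested with edgeR 4.0.16 (estimateDisp, glmQLFit and glmQLFTest, two-sided, treatment as the only term), and p-values were adjusted by Benjamini-Hochberg over all genes kept, with a threshold of 0.05. Standard errors were taken from the log2 fold change and the F statistic. Levels are counts scaled by TMM library sizes (CPM), given as mean ± SD. The common biological coefficient of variation was 19.5%. Data were simulated from the means and library sizes of these 6 libraries, with 13473 genes in the fit. Each run held 100 genes changed 2-fold and 100 changed 4-fold. The same test recovered 48.2% of genes changed 2-fold and 88.4% of genes changed 4-fold, and 8.08% of its calls were unchanged genes. It made 148.6 calls per run on average, where the real libraries gave 4, so its p-value cut was less strict. The simulated genes also varied independently of each other. The recovery may therefore overstate that in the real libraries.

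Before the data were examined, 51 gene lists for lung cell types, fibrosis, immune pathways, cell state and library quality were fixed, along with the test of each result and the rule for the genes named. Lists with at least 5 tested members, 47 in all, were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with an estimated correlation and fry were run beside it. At the preset correlation camera's degrees of freedom come from the number of genes. Its p-values then rest on the genes and on the preset correlation, and do not measure the spread between samples. With an estimated correlation the degrees of freedom come from the few libraries, which makes the test far less sensitive. The fry test asks whether the members of a list move, on balance, in 1 direction, and does not compare the list with other genes. For each list, p-values of its members were also adjusted over the list alone. That adjustment takes no account of the number of lists, so it does not limit false calls across them. The rule named the 3 genes of C1q itself, the called genes with the largest changes in either direction whose 3 C1q libraries all lay outside the range of the 3 saline libraries at a mean CPM of at least 5, the leading members of each list, and the 5 genes with the smallest p-value in a direction with fewer than 5 calls. Other members of a list, and the genes singled out in the closing part, were chosen after their values were seen.

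The share of counts taken by haemoglobin genes, ribosomal protein genes and the 20 most abundant genes was compared by an exact permutation test, two-sided, which at 3 against 3 cannot give less than p = 0.1. Mitochondrially encoded transcripts and immunoglobulin genes had no entry in the table analysed here. Gene positions come from GENCODE M21 on GRCm38, matched by symbol for 12757 of the 13473 genes tested.

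Alternatives covered other scalings, DESeq2 1.42.0, limma-voom with and without sample weights, robust fitting, other filters and thresholds, removal of transcript classes and the removal of each library in turn. Chosen after seeing the data were a fit with 1 surrogate variable (svaseq, sva 3.50.0), removal of the single most abundant entry, LOC118568312, and removal of a set of genes more than 4-fold (on CPM + 1) above every saline library in C1q replicate 2. That set was first picked with C1q replicate 3 also among the reference libraries, and was redefined on the saline libraries alone so that C1q replicates 1 and 3 stayed free for a test. The analysis ran in R 4.3.3, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.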

Results

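The response of the mouse lung to C1q was measured in 6 libraries of digested lung cells, 3 from saline-treated and 3 from C1q-treated animals, at day 3. C1q is the recognition subunit of the classical complement pathway. Saline was the only control, so an effect particular to C1q cannot be told from an effect of instilled protein in general. Total counts were 2991562, 2658913 and 2577429 in saline replicates 1 to 3 and 3650793, 2980053 and 2227619 in C1q replicates 1 to 3. Between 20520 and 23259 genes had a count, the highest number being in saline replicate 3. At these depths 3 counts correspond to 0.822 to 1.35 CPM, and genes near that level were measured with little precision.

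Lung cells of C1q-treated mice had more transcript of 4 genes. Retnla, which encodes a secreted protein of alternatively activated macrophages and airway cells, rose 4.41-fold, from 53.7 ± 2.25 to 237 ± 58.5 CPM (SD, n = 3 each). Eln, which encodes the elastic fibre protein elastin, rose 3.30-fold, from 157 ± 22.1 to 518 ± 73.1 CPM. Timp1, an inhibitor of matrix metalloproteinases, rose from 11.8 ± 2.1 to 35.8 ± 0.725 CPM. Kcne4, a regulatory subunit of potassium channels, rose from 14.0 ± 2.82 to 42.5 ± 6.45 CPM.

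These were the 4 genes of 13473 that passed the edgeR test, all higher after C1q and with all 3 C1q libraries above all 3 saline libraries. In the lower direction 0 genes passed, and 531 had an unadjusted p under 0.05. There DESeq2 called 1, and some other edgeR fits given below called more lower than higher genes. The log2 fold changes were 2.14 ± 0.19 (SE) for Retnla (adjusted p = 0.00411), 1.72 ± 0.18 for Eln (adjusted p = 0.00723), 1.60 ± 0.20 for Timp1 (adjusted p = 0.0316) and 1.59 ± 0.21 for Kcne4 (adjusted p = 0.0411). Without saline replicate 1 the adjusted p was 0.126 for Retnla and Eln, 0.471 for Timp1 and 0.598 for Kcne4, and without C1q replicate 1 it was 0.0871 for Eln, 0.297 for Timp1 and 0.329 for Kcne4. Timp1 and Kcne4 also failed without C1q replicate 2 (0.109 for both) and without C1q replicate 3 (0.0704 and 0.0890), and Kcne4 with upper-quartile scaling (0.0528), library size only (0.0979) and limma-voom (0.0651). On GRCm38, Retnla lies on chromosome 16 from 48842551 to 48844461, Eln on chromosome 5 from 134702593 to 134747323, Timp1 on chromosome X from 20870166 to 20874735 and Kcne4 on chromosome 1 from 78816758 to 78820028, each annotated as protein-coding. The macrophage metalloelastase gene Mmp12 had a log2 fold change of 2.45 ± 0.36 at 1.81 ± 0.164 CPM in saline and 10.1 ± 0.563 CPM in C1q, and missed the threshold (adjusted p = 0.0905). Il5, the eosinophil growth factor, had a log2 fold change of 3.00 ± 0.45 at a saline level of 1.12 ± 0.434 CPM (adjusted p = 0.0906).

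Across all genes, 1099 had an unadjusted p under 0.05, where 673.65 would be met by chance, 568 of them with a higher and 531 with a lower mean after C1q. All 3 C1q libraries lay above the saline range for 1094 genes and below it for 803, together 14.1% of genes where chance gives 10%. The lower genes with the smallest p-values did not pass: Fendrr had a log2 fold change of -0.84 ± 0.16, Adrb1 of -1.46 ± 0.28, Snhg11 of -1.29 ± 0.29, Adamts13 of -1.08 ± 0.25 and Crim1 of -0.59 ± 0.14, with adjusted p from 0.231 to 0.383. The number of calls was 0 without saline replicate 1, 10 without saline replicate 3, 1 without C1q replicate 1, 2 without C1q replicate 2 and 5 without C1q replicate 3, of which 2 were among the 4 and 3 were genes in excess in C1q replicate 2. DESeq2 called 32 genes, 3 of them from that excess set. With no filter on low counts edgeR called 373, of which 158 were higher and 26 of these were the whole set. With 1 surrogate variable, a fit chosen after seeing the data, edgeR called 359, of which 136 were higher.

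**Figure D1:**
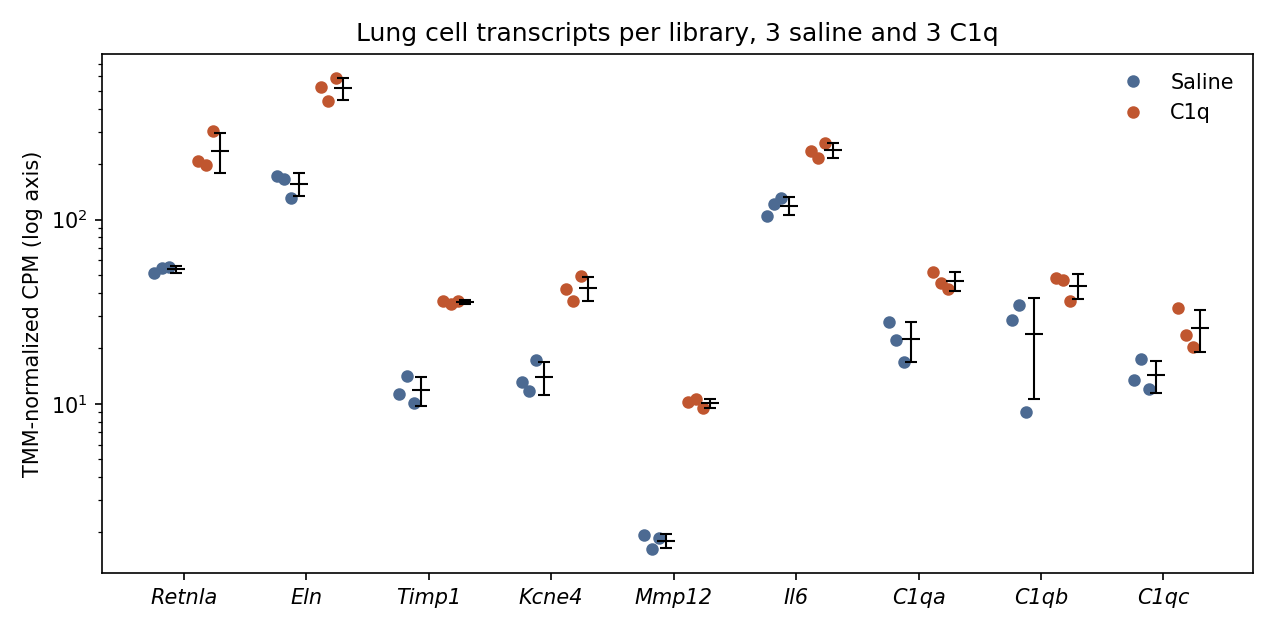
TMM-normalized CPM on a log axis for 9 genes in each library, blue for saline and orange for C1q, with the mean and SD of each group in black (n = 3). Retnla, Eln, Timp1 and Kcne4 passed the edgeR test; for Mmp12, Il6, C1qa, C1qb and C1qc the groups did not overlap but the adjusted p was 0.0905 or more.

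The genes of C1q itself, which lie next to each other on chromosome 4, were higher on average in the treated lungs without passing over all genes. C1qa was at 22.3 ± 5.58 CPM in saline and 46.5 ± 5.27 CPM in C1q, a log2 fold change of 1.05 ± 0.21 (adjusted p = 0.231). C1qb had a log2 fold change of 0.88 ± 0.35 (adjusted p = 0.602), which was 0.49 without saline replicate 3, and C1qc of 0.87 ± 0.25 (adjusted p = 0.484). C1qa spans 136895917 to 136898803, C1qb 136880129 to 136886187 and C1qc 136889804 to 136893065. In the complement list, 6 of 20 tested members rose when adjusted over the list alone and 0 over all genes. Besides C1qa and C1qc these were Clu, an inhibitor of the terminal complex, at a log2 fold change of 1.13 ± 0.24, Cfp, which encodes properdin, at 0.82 ± 0.18, and the anaphylatoxin receptors C3ar1 at 1.17 ± 0.36 and C5ar1 at 0.57 ± 0.19. The list was called higher by camera (adjusted p = 4.60e-07), with adjusted p = 0.281 with an estimated correlation. Among 9 tested proposed receptors of C1q, 0 passed adjusted over the list alone or over all genes, Cd44 being at 0.31 ± 0.14 and Cd93 at -0.34 ± 0.17 (-0.51 without C1q replicate 2).

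Genes for the extracellular matrix were higher on average after C1q. All 28 tested members had a positive log2 fold change with a median of 0.57, and 16 rose when adjusted over the list alone, with 1, Eln, over all genes. The fibrillar collagen genes were among the 16: Col3a1 went from 329 to 808 CPM (log2 fold change 1.30 ± 0.26), Col1a1 from 165 to 328 CPM (0.99 ± 0.20) and Col1a2 from 241 to 436 CPM (0.86 ± 0.16). Others in this group were Col5a1 at 0.84 ± 0.16, the proteoglycan gene Bgn at 0.70 ± 0.15, Fn1 at 0.73 ± 0.18 and Loxl1, an elastin crosslinking enzyme, at 0.66 ± 0.15. The list was called higher by camera (adjusted p = 2.78e-17), with adjusted p = 0.148 with an estimated correlation, and by fry (adjusted p = 0.0249).

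Enzymes that cut the matrix and their inhibitors were shifted in the same direction. Of 16 tested members, 8 rose when adjusted over the list alone and 1, Timp1, over all genes. The 8 were Timp1, Mmp12, Mmp19 at a log2 fold change of 0.89 ± 0.16, Adamts2 at 0.82 ± 0.16, Mmp2 at 1.02 ± 0.20, Adamts4 at 1.18 ± 0.26, Adam8 at 0.88 ± 0.23 and Mmp14 at 0.63 ± 0.17. Camera called the list higher (adjusted p = 1.29e-08), with adjusted p = 0.148 with an estimated correlation, and fry did so too (adjusted p = 0.0235).

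Fibroblast markers moved unevenly. Of the 17 tested members of the fibroblast identity list, 5 rose when adjusted over the list alone and 0 over all genes: the microfibril genes Mfap4 (585 to 1256 CPM, log2 fold change 1.10 ± 0.19) and Mfap5 (0.72 ± 0.19), the adventitial fibroblast marker Pi16 (0.66 ± 0.21), Clec3b (0.53 ± 0.17) and Dpt (0.48 ± 0.16). Pdgfra, a general marker of lung fibroblasts, was at 0.08 ± 0.15 (-0.0416 without C1q replicate 2), Tcf21 at 0.24 ± 0.14, Npnt at 0.22 ± 0.15, Col13a1 at -0.00375 ± 0.15 (-0.0727 to 0.0665 with 1 library left out) and Inmt at -0.21 ± 0.23 (-0.0279 without saline replicate 2, -0.41 without saline replicate 3 and -0.0624 without C1q replicate 3). The list was called higher by camera (adjusted p = 0.000105), with adjusted p = 0.348 with an estimated correlation. Of 11 smooth muscle and myofibroblast genes, 0 passed adjusted over the list alone or over all genes, and Acta2 stood at 262.6 ± 31.6 CPM in saline and 263.5 ± 41.6 CPM in C1q.

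Growth factor and cytokine genes that act on fibroblasts had 7 members higher and 1 lower of 14 tested when adjusted over the list alone, and 0 over all genes. The higher ones included Ereg, an EGF receptor ligand, at a log2 fold change of 2.15 ± 0.45 from a saline level of 1.77 CPM, Igf1 at 0.96 ± 0.20, Osm at 0.69 ± 0.21, the alarmin gene Il33 at 0.55 ± 0.17 and Spp1 at 0.54 ± 0.18. Pdgfa was the lower one, at -0.59 ± 0.20 (-0.36 without saline replicate 3). Camera called the list higher (adjusted p = 0.000117), with adjusted p = 0.281 with an estimated correlation. The TGF-beta response list was not called (adjusted p = 0.271), with Tgfbi at 0.65 ± 0.22 and Ccn2, a direct target of the pathway, at -0.76 ± 0.23, and 0 of its 16 members passed adjusted over the list alone or over all genes. The Wnt/beta-catenin list was not called either (adjusted p = 0.886), its leading members being Tcf7 at -0.70 ± 0.20 and Lef1 at -0.44 ± 0.24 (-0.28 without C1q replicate 3).

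Macrophage activation genes were also higher. In the alternative activation list, 4 of 9 tested members rose when adjusted over the list alone, and 1, Retnla, over all genes. The others were Chil3, a chitinase-like lectin, which stood at 1369 ± 641 CPM in saline and 2558 ± 233 CPM in C1q, Clec7a at a log2 fold change of 0.61 ± 0.16 and Arg1 at 1.19 ± 0.41. The list was called by camera (adjusted p = 3.53e-06), with adjusted p = 0.148 with an estimated correlation, and by fry (adjusted p = 0.0235). Of 15 lipid-associated and profibrotic macrophage genes, Mmp12 and Ctsk, a collagen-degrading cathepsin at 0.84 ± 0.22, rose when adjusted over the list alone and 0 over all genes. Camera called that list too (adjusted p = 9.67e-07), with adjusted p = 0.381 with an estimated correlation.

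Inflammatory cytokine genes were higher in the C1q libraries, by about 2-fold for the leading members. Il6 went from 119 ± 13.1 to 238 ± 22.9 CPM and Cxcl1, a neutrophil attractant, from 97.2 ± 15.6 to 201 ± 27.1 CPM. With Il1b at a log2 fold change of 0.77 ± 0.15 and Il1rn, the interleukin-1 receptor antagonist, at 0.56 ± 0.16, they made 4 of 17 tested members that rose when adjusted over the list alone, and 0 did over all genes. The list was called by camera (adjusted p = 9.86e-06), with adjusted p = 0.148 with an estimated correlation, and by fry (adjusted p = 0.0307). In the chemokine list, Ccl9 (0.91 ± 0.22), Ccl7 (0.65 ± 0.17), Cxcl10 (0.87 ± 0.26) and Ccl2 (0.64 ± 0.21) were the 4 of 15 that rose when adjusted over the list alone, against 0 over all genes, while Ccl5 was at -1.0 ± 0.41 (-0.61 without saline replicate 2). Camera called the chemokines higher (adjusted p = 0.00718), with adjusted p = 0.494 with an estimated correlation and 0.197 without saline replicate 3.

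Cell cycle genes had the largest median shift of any list called, at low levels. The median log2 fold change was 1.29, and 9 of 16 tested members rose when adjusted over the list alone and 0 over all genes, including Ccna2 (2.82 to 13.6 CPM), Top2a (6.16 to 19.6 CPM) and Cdk1 (2.47 to 13.7 CPM). The shift was uneven between C1q libraries: Top2a stood at 27.7, 8.47 and 22.6 CPM in replicates 1 to 3, and Cdk1 at 24.1, 3.53 and 13.5 CPM. Camera called the list higher (adjusted p = 5.48e-09), with adjusted p = 0.348 with an estimated correlation.

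The remaining lists called higher were small shifts. In the hypoxia and glycolysis list the median log2 fold change was 0.19 and 0 of 14 members passed adjusted over the list alone or over all genes, with Ldha at 0.41 ± 0.14 (camera adjusted p = 0.0265, and adjusted p = 0.348 with an estimated correlation). In the oxidative stress list 1 of 13 members, the haem oxygenase gene Hmox1, rose when adjusted over the list alone, from 67.1 ± 9.97 to 120.4 ± 12.8 CPM, and 0 over all genes (camera adjusted p = 0.0265, and adjusted p = 0.381 with an estimated correlation). Without saline replicate 1 or saline replicate 3 neither list passed, with adjusted p of 0.0745 and 0.129 for hypoxia and 0.12 and 0.11 for oxidative stress. The hypoxia list also failed without C1q replicate 2 (0.0531) and without C1q replicate 3 (0.0520).

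Vascular genes lay on the other side. All 13 pan-endothelial genes had a negative log2 fold change with a median of -0.24, and 0 passed adjusted over the list alone or over all genes, Ramp2 being at -0.43 ± 0.21 (-0.26 without saline replicate 2 and -0.27 without C1q replicate 3) and Kdr, a VEGF receptor, at -0.33 ± 0.17. Camera called the list lower (adjusted p = 0.00967), with adjusted p = 0.518 with an estimated correlation. Of 10 pericyte genes, 0 passed adjusted over the list alone or over all genes, Higd1b being at -0.87 ± 0.25 and Cox4i2 at -0.60 ± 0.20 (camera adjusted p = 0.0169, and adjusted p = 0.281 with an estimated correlation). Without saline replicate 1, C1q replicate 1 or C1q replicate 3 the adjusted p was 0.11, 0.0779 and 0.117 for the endothelial list and 0.109, 0.0555 and 0.0653 for the pericyte list.

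T cell genes were at low levels throughout. All 9 tested had a negative log2 fold change, 0 passed adjusted over the list alone or over all genes, and Cd3e stood at 6.22 ± 1.19 CPM in saline and 3.11 ± 1.47 CPM in C1q. Camera called the list lower (adjusted p = 0.0154), with adjusted p = 0.348 with an estimated correlation, 0.167 without saline replicate 1 and 0.0859 with the stricter filter on low counts. The list of genes induced by tissue dissociation and other immediate-early genes was lower in the C1q libraries as well, with Hspa1b at -0.61 ± 0.18 and Egr1 at -0.40 ± 0.14 and 0 of 18 members passing adjusted over the list alone or over all genes. Its camera call (adjusted p = 0.0474, and adjusted p = 0.503 with an estimated correlation) did not hold without saline replicate 1 (0.205), saline replicate 2 (0.0970), C1q replicate 1 (0.101) or C1q replicate 3 (0.182), nor without the genes in excess in C1q replicate 2 (0.0502), a set chosen after seeing the data.

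**Figure D2:**
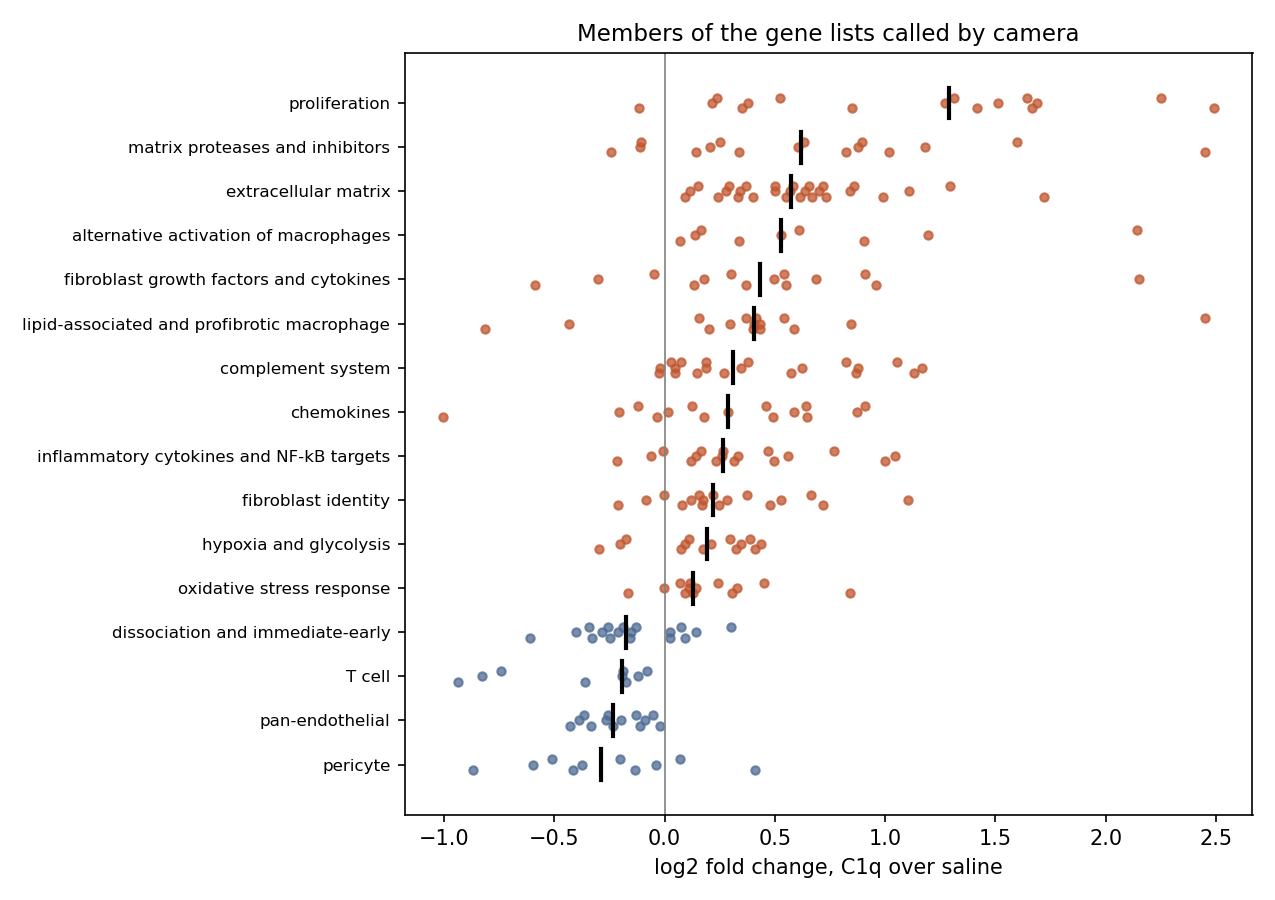
Log2 fold change, C1q over saline, of each tested member of the 16 lists called by camera at its preset correlation, orange for lists called higher and blue for lists called lower, with the median of each list as a black bar. The medians run from 1.29 for proliferation to -0.29 for pericyte genes, and none of the 16 calls held with an estimated correlation.

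In all, camera called 12 of 47 lists higher and 4 lower at its preset correlation, 0 with an estimated correlation (smallest adjusted p = 0.148), and fry called 4, all higher. Calls were also lost where the estimate lay below the preset 0.01, as for alternative activation (0.00099) and pericyte genes (-0.0145). A high correlation alone therefore does not account for the loss. With an estimated correlation the degrees of freedom also come from the libraries instead of the genes, which lowers sensitivity at any correlation. Of the 16 calls, 9 held whichever single library was removed, and 7 were lost in at least 1 of these removals. Markers of most resident and blood-derived cell types were not called. The alveolar macrophage list had a median log2 fold change of 0.15 (adjusted p = 0.101), the alveolar type 2 list of 0.22 (0.0882), the neutrophil list of 0.26 (0.175), the classical monocyte list of 0.13 (0.228) and the interstitial macrophage list of 0.13 (0.138), in which C1qa and C1qc alone rose when adjusted over the list alone and 0 genes over all genes. The group 2 innate lymphoid cell list was not called (0.616), although Il5 rose when adjusted over the list alone and 0 genes did over all genes; its median log2 fold change was -0.09 and its mean 0.36. Lists for B cells (0.147), natural killer cells (0.271), interferon-stimulated genes (0.237) and ciliated cells (0.147) had negative medians without a call. The median and mean also differed in sign for the Wnt/beta-catenin list (0.06 and -0.01) and for the megakaryocyte and platelet list (0.09 and -0.08, adjusted p = 0.705). The other lists tested gave adjusted p from 0.0763 to 0.742, and 4 lists, for eosinophils, for basophils and mast cells, for erythroid cells and for mitochondrially encoded transcripts, had under 5 tested members. Outside the lists called, Msln rose when adjusted over the list alone (log2 fold change 1.03 ± 0.32, with overlapping groups). Its mesothelium list had a median of -0.07 with 1 of 5 members positive. Gata2 of the basophil and mast cell list fell when adjusted over the list alone (-0.45 ± 0.16), where only 2 of 10 members were tested. The other was Cma1 at -0.06 ± 0.56. Over all genes 0 passed in either list.

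Haemoglobin genes took 0.0179% ± 0.00914 of the counts in saline and 0.0102% ± 0.00770 in C1q (exact permutation p = 0.4), and ribosomal protein genes 3.95% ± 1.32 and 3.29% ± 0.418 (exact permutation p = 0.6), where 0.1 is the smallest p that 3 against 3 allows. The ribosomal protein share was 5.29% in saline replicate 2 and 2.66% in saline replicate 3. Saline replicate 3 stood farthest out on the first principal component, which held 39.1% of the variance, with saline replicate 2 at the opposite end. The second component, with 24.7% of the variance, separated the groups, at 9.20 to 34.9 in saline and -21.0 to -16.6 in C1q. The single entry LOC118568312 took 9.77% ± 2.43 of the counts in saline and 11.7% ± 1.85 in C1q (exact permutation p = 0.3).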

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

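Chosen after seeing the data were the fits with 1 surrogate variable, without the genes in excess in C1q replicate 2 and without LOC118568312; the other alternatives were planned. The count of 4 genes, 4 higher and 0 lower, was 3 or 4 with other scalings, limma-voom, robust fitting, the stricter filter, without the transcript classes, without the excess genes and without LOC118568312, and 6 at an adjusted p of 0.1. DESeq2 called 32 genes (31 higher, 1 lower) and limma-voom with sample weights 19, all higher, and each included the 4; 3 of the 31 were genes in excess in C1q replicate 2. With no filter on low counts edgeR called 373 (158 higher, among them all 26 excess genes, and 215 lower), 356 of them genes that the filter kept. The prior degrees of freedom of the quasi-likelihood dispersion went from 6.73 to infinite, so that each gene took the spread of the trend at its level. With 1 surrogate variable, which set saline replicate 3 against saline replicate 2, 359 genes were called (136 higher, with 8 excess genes, and 223 lower), the 4 among them, and the cause was not tested. Leaving out 1 library gave 0 to 10 calls, 0 to 9 higher and 0 to 1 lower: 0, 5 and 10 without saline replicates 1, 2 and 3, with 0, 4 and 4 of the 4 genes among them, and 1, 2 and 5 without C1q replicates 1, 2 and 3, with 1, 2 and 2 of them; the other 3 without C1q replicate 3 were excess genes. Fewer samples enter these fits. Retnla failed without saline replicate 1 only (adjusted p = 0.126; 0.00195 to 0.0391 without the others), and Eln without saline replicate 1 (0.126) and C1q replicate 1 (0.0871). Timp1 and Kcne4 failed without saline replicate 1 (0.471 and 0.598), C1q replicate 1 (0.297 and 0.329), C1q replicate 2 (0.109 for both) and C1q replicate 3 (0.0704 and 0.0890), and Kcne4 also with upper-quartile scaling (0.0528), library size only (0.0979) and limma-voom (0.0651). With each library left out the log2 fold change was 1.93 to 2.26 for Retnla, 1.61 to 1.83 for Eln, 1.5 to 1.74 for Timp1 and 1.49 to 1.76 for Kcne4.

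Of the gene lists, 12 higher and 4 lower became 0 and 0 with an estimated correlation. For these it was -0.0145 (pericyte) to 0.591 (proliferation), preset 0.01. Fry, which compares no list with other genes, left 4 and 0. Leaving out 1 library gave 10 to 20 higher and 0 to 7 lower, 20 higher without saline replicate 2, and 0, 7 and 1 lower without saline replicate 1, saline replicate 3 and C1q replicate 3. Directions turned for values that did not pass: as log2 fold changes over the libraries left out, Cox6a2 went from -1.97 to 0.0359 (without saline replicate 2), Il5ra from -0.48 to 0.15 (without C1q replicate 2), Cma1 from -0.43 to 0.36 (without saline replicate 1; also positive without saline replicate 2 and without C1q replicate 3) and Itgb3 from -0.0774 (without C1q replicate 3) to 0.23, and Cma1 was at 0.00325 with limma-voom. Values near 0 turned too: Col13a1 from -0.0727 to 0.0665 and Pdgfra from -0.0416 to 0.15 over the libraries left out, and Acta2, at 0.00685, from -0.0960 (without C1q replicate 1) to 0.131 (without C1q replicate 3), -0.000762 with RLE size factors, -0.0271 with library size only, -0.000108 with DESeq2, -0.00157 with limma-voom, -0.00335 with the stricter filter and -0.0691 with 1 surrogate variable. The difference in ribosomal protein share, in percent of counts, was -0.659 and ran from -1.31 without saline replicate 3 to 0.0117 without saline replicate 2. The cause was not tested for any of these. No paired analysis was possible because the labels give no shared replicate numbers. At 2227619 to 3650793 counts per library and 3 libraries per group, simulated 2-fold changes were recovered in 48.2% of cases. That was at a less strict p-value cut than in the real data. A gene that did not pass is therefore not shown to be unchanged.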

Other observations

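The tests of splits of the libraries and of intron length were set before their results were seen; those of the matrix genes, of the genes in excess in C1q replicate 2 and of depth were chosen after. The following genes outside the lists were picked for their values and did not pass the edgeR test, so they support no theme. Tnfaip6, which encodes a hyaluronan-binding protein induced by inflammation, stood at 46.9 ± 4.26 CPM in saline and 114 ± 31.0 CPM in C1q (log2 fold change 1.27 ± 0.21, adjusted p = 0.118). Serpinb2, a plasminogen activator inhibitor, was at 2.03 ± 0.539 and 10.6 ± 1.87 CPM (2.36 ± 0.38, adjusted p = 0.118), and the lipopolysaccharide co-receptor gene Cd14 at 155 ± 11.3 and 256 ± 29.6 CPM (0.73 ± 0.15, adjusted p = 0.277). Krt15, a basal airway keratin, was at 1.73 ± 1.74 and 13.9 ± 9.36 CPM (3.03 ± 0.66, adjusted p = 0.281).

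Among the 10 splits of the 6 libraries into 3 and 3, the real one was the 1 split that called 4 genes, and the highest of the others called 0. For gene lists the real split was the 1 with 16 calls, while the 9 others called 2 to 12, so camera at its preset correlation also called lists between mixed groups. Each of those mixed splits was unbalanced between the treatments, so part of a treatment difference remained. Their calls are thus not those expected without any treatment difference. With 10 splits no share under 0.05 can be reached.

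For the higher level of matrix genes, a larger share of every kind of fibroblast in the C1q suspensions would raise fibroblast markers as much, but the median log2 fold change of the matrix list lay 0.356 above that of the fibroblast identity list (permutation p = 0.00351 over genes, which are not independent). Per library, however, C1q replicate 2 overlapped the saline range in this difference, at -0.552 against -0.438 in saline replicate 3, so a shift in cell composition and a change per cell cannot be told apart. A bias by transcript length was argued against by 995 genes matched to the matrix genes on exonic length and level, whose median log2 fold change was 0.0103. A single library as the source was argued against by the mean difference of the list in log2 CPM, 0.588 with all libraries and 0.545 to 0.651 in new fits with 1 left out; from the library means of the first fit it was 0.539 to 0.649 with 1 left out, with a lowest 95% limit of 0.218. A response of matrix-producing cells to C1q and a rise of 1 fibroblast subtype both stay open.

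In C1q replicate 2, 26 genes lay more than 4-fold above every saline library, led by 2810407A14Rik at 3462 CPM against 20.0 ± 5.47 CPM in saline (here without TMM scaling), then Tnfrsf26 at 1068 against 6.39 ± 2.61 CPM. They lie on 12 chromosomes where the 20 with a position are placed. C1q replicate 1 held the same genes above saline for 25 of the 26, at a near-constant proportion: the excess there was 0.165 of that in replicate 2 at the median, with an upper quartile 1.36 times the lower one. C1q replicate 3 did not share it, with a median log2 ratio of -0.0866 to the saline mean, which argues against a response to C1q. A source common to the 2 libraries, such as sequence carried over from 1 preparation, may account for it, and its nature was not identified.

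Saline replicate 3 differed from the other libraries in the kind of genes it held. Genes in the upper tertile of intron length lay 0.349 log2 units above those in the lowest tertile in saline replicate 3, relative to the other 5. The next highest value was 0.148 in C1q replicate 3, and the lowest was -0.214 in saline replicate 2. By exonic length, the lowest tertile minus the upper one was -0.426 in saline replicate 3 and 0.239 in saline replicate 2. Intron length and transcript length are therefore not told apart. The intron value had the direction predicted for more reads from unspliced RNA or genomic DNA there, but it cannot decide on them. Transcript length changed with it. A count limited to transcript starts would not rise with intron length in unspliced RNA, but whether the counts were so limited is not given. Low depth does not account for the position of saline replicate 3. In it 23259 genes had a count, against at most 21749 in any other library, including deeper ones. Between the treatment groups the difference between the intron tertiles in log2 fold change was -0.03. Genes not annotated as protein-coding did separate the groups. Their median log2 deviation from the other 5 libraries was 0.0326 to 0.120 in saline and -0.181 to -0.0753 in C1q. The cause of that was not tested. For saline replicate 3 no biological explanation was tested, since the design gives none for a single library.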
